A study of Mus musculus with 10 samples.

How the data were processed

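The series holds bulk RNA-seq of mast cells sorted by flow cytometry from the lower airways of wild-type C57BL/6 mice of 5 to 7 weeks. Per the labels' protocols, cells went straight into lysis buffer, and libraries were made with SmartSeq2, in which poly(A)+ mRNA is copied to cDNA, amplified and fragmented by a transposase. Sequencing was paired-end with reads of 25 nt. The 10 libraries fall into 4 groups by sorted population and challenge: B7hi with saline (n = 2), B7low with saline (n = 2), B7hi with house dust mite extract (HDM, n = 3) and B7low with HDM (n = 3). The group and the replicate number were read from each sample's title.

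The deposited file is a table of raw counts, whole numbers per gene symbol, with 22815 symbols and 1 column per library. The submitters' processing notes name TopHat2 2.0.10, Cufflinks 2.2.1, DESeq2 and the mouse build mm10, with no role given for each. The step that counted reads, its annotation and its use of strand are not given in the sources used here. Reads from a gene and an antisense partner therefore cannot be told apart, and reads of 25 nt shared by close relatives, such as Mcpt1 and Mcpt2, Tpsb2 and Tpsab1 or the Mrgpr genes, may have been split between them. Coordinates in the text come from GENCODE M21 on GRCm38, which is the build called mm10, and are 1-based. A RefSeq table of the same assembly held 21355 of the 22815 symbols.

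Total counts per library ran from 525983 (B7hi HDM 2) to 1725818 (B7hi saline 2). A count of 0 in a library therefore allows a level of up to 5.70 CPM at the lowest depth and 1.74 CPM at the highest (3 counts over the library's total). Such limits and the exact binomial 95% intervals given for shares cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Of the 22815 symbols, 3029 had no count in any library and 10533 passed edgeR's filterByExpr over the 4 groups. The tested genes held 98.2% to 99.5% of each library's counts. Within groups, pairs of libraries differed by far more than sampling noise, with a chi-square per degree of freedom of 6.74 to 11.1, so none looks like another library deposited again. Every library was counted as its own replicate, as labelled, although amplification alone could give such a spread.

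Counts were scaled by TMM and fitted with edgeR 4.0.16 (R 4.3.3) as a quasi-likelihood model with robust spread estimates, with 1 mean per group and all 10 libraries in the same fit. The common biological coefficient of variation was 0.359. Each of 5 contrasts was tested two-sided: B7hi against B7low with saline, the same with HDM, HDM against saline in B7hi, the same in B7low, and the interaction, which is the HDM effect in B7hi minus that in B7low. Adjusted p-values are Benjamini-Hochberg values over the 10533 genes, with a threshold of 0.05. Levels in the text are in CPM of the TMM-scaled library size, as mean ± SD over libraries. The SE given with log2 fold changes is approximate. It was derived from the test, as the size of the log2 fold change over the square root of its F statistic. Where the lower group had 0 counts, the fold is a lower bound against 3 counts over that group, and where it had 1 to 3 counts, the fold is a ratio with an exact 95% counting interval.

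Gene lists for mast cell programs, signalling, metabolism and markers of other cell types were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 30 lists with at least 3 tested genes. The same lists were also tested with camera with an estimated correlation and with fry. No list passed 0.05 with the estimated correlation in any contrast, where the lowest adjusted p was 0.20, 0.31, 0.29, 0.52 and 0.42 in the order of contrasts above. Each list call in the text is therefore a call of camera with the preset correlation. Fry kept 6 of the 11 such calls for B7hi against B7low with saline and 2 of the 10 with HDM, and 0 in the other contrasts. With saline, fry is named for the connective tissue list alone. The comparisons, tests, lists and alternatives were fixed before the data were examined.

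The genes named are, for each contrast, up to 10 with the largest and 10 with the smallest fitted log2 fold change among those past the threshold with at least 20 CPM in the higher group, a symbol that is not a predicted model and CPM ranges that do not overlap. To these come up to 4 members with the smallest p of each list described, and a fixed set in every contrast (Itgb7, Itgae, Kit, Fcer1a, Cpa3, Cma1, Mcpt4, Tpsb2, Mcpt1, Mcpt2, Mrgprb2, Ltc4s, Cd34 and Mki67). Ltc4s did not pass the count filter. Marker genes of other cell types are named for their level. Some genes that the rule names are not reported here.

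The alternatives were DESeq2 size factors or library size alone in place of TMM, DESeq2 1.42.0 or limma-voom with quality weights in place of edgeR, no count filter, a filter of at least 5 CPM in 2 libraries, only the groups compared, a replicate block, no robust estimation and leaving out each library in turn. Chosen after seeing the data were runs without the ribosomal RNA precursor Rn45s and without the 2 libraries highest in the long noncoding RNA Kcnq1ot1. The steps were tested on simulated counts drawn from each gene's mean over all 10 libraries, with the real library sizes and genes changed by known folds. Before these changes the groups thus had the same means. For B7hi against B7low with saline (10119 genes), 0% of the 2-fold, 34.8% of the 4-fold and 81.6% of the 16-fold changes were recovered. The shares were 14.9%, 57.4% and 90.0% with HDM (10022 genes), 2.13%, 61.7% and 79.2% for HDM against saline in B7hi (10082 genes), and 19.1%, 42.0% and 76.0% in B7low (10094 genes). For the interaction (10050 genes) they were 0%, 18.8% and 61.2%. No more than 10 genes were called falsely in any of these runs. Camera with the preset correlation found the planted list in each run, and also called 2 unchanged lists for HDM against saline in B7hi and 0 in the other 4 contrasts. The genes were drawn independently of each other, so these runs cannot show how often camera calls lists of correlated genes. Figures were drawn with matplotlib 3.10.9.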

Results

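Mast cells were sorted from the mouse lower airway as 2 populations, B7hi and B7low, after intranasal challenge with 20 µL of saline or of saline with 3 µg HDM extract, 2 times a week for 3 weeks. HDM extract is an allergen preparation widely used to elicit airway inflammation in mice. The series title names the cells inducible and constitutive mast cells, and in the published use of these names B7 is integrin β7, with inducible cells the β7-high and constitutive cells the β7-low population. Total counts were 1222409 and 1725818 in B7hi with saline, 652736 and 639906 in B7low with saline, 1699667, 525983 and 1419336 in B7hi with HDM, and 771519, 1501225 and 1572427 in B7low with HDM. The labels do not say whether replicates came from separate animals or pools, so p-values measure the spread between these libraries, which may be partly technical.

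Mast cell transcripts were abundant in every library. Cpa3, the mast cell carboxypeptidase, ranged between group means of 5186 and 20638 CPM, and the stem cell factor receptor Kit between 3331 and 5349 CPM. The ribosomal RNA precursor Rn45s took 19.7% (exact binomial 95% interval 19.6 to 19.7) to 28.9% (28.8 to 29.0) of counts, with group means of 20.6% in B7hi and 28.1% in B7low with saline, and 24.2% and 23.6% with HDM. The first principal component, 33.3% of the variance, separated B7hi from B7low. The second, 18.4%, set apart B7low saline 2 and B7hi HDM 2, in which Kcnq1ot1 stood at 6956 and 12133 CPM against 806 to 2794 CPM in the other 8 libraries. These 2 libraries also had the lowest total counts (639906 and 525983). B7low saline 1, nearly as low at 652736, lay at the opposite end of this component.

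**Figure D1:**
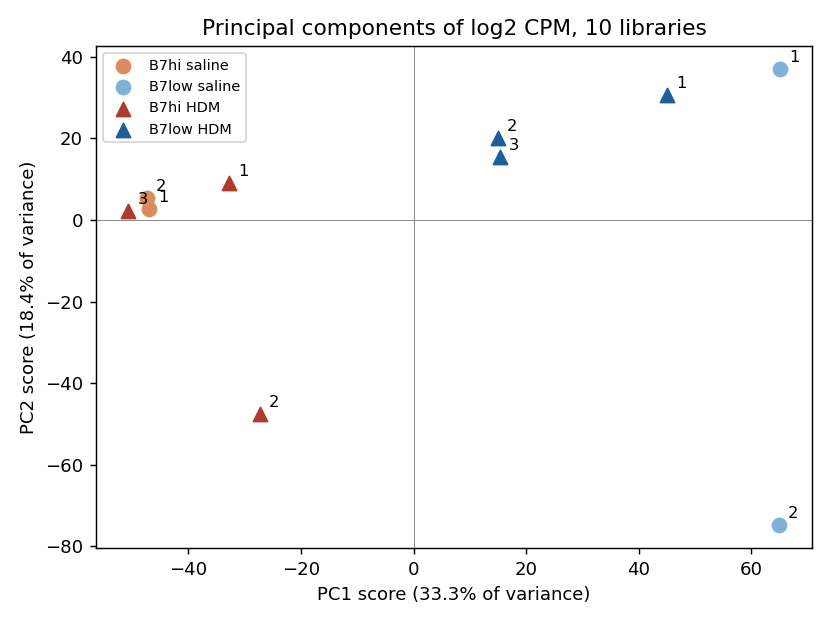
Scores of the 10 libraries on the first (33.3% of variance) and second (18.4%) principal component of log2 CPM, colored by population and shaped by challenge. The 5 B7hi libraries lie below 0 on the first component and the 5 B7low libraries above 0, and B7low saline 2 and B7hi HDM 2 lie lowest on the second.

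The first comparison asks how inducible and constitutive mast cells differ without allergen. With saline, B7hi cells had far lower levels of the granule proteases and receptors that mark connective tissue mast cells. The chymase Cma1 (chromosome 14, 55941451 to 55944675) stood at 1766 ± 228 CPM in B7hi and 25771 ± 12083 CPM in B7low (SD, n = 2 each), a log2 fold change of −3.87 ± 0.38 (SE, edgeR adjusted p = 1.8e-05). Mcpt4, a second chymase of the same locus (56059629 to 56062313), differed by −5.76 ± 0.72, the tryptase Tpsb2 by −5.10 ± 0.71 and the adenosine receptor Adora3 by −3.25 ± 0.33. The orphan receptor Mrgprb1 was at 5.43 ± 6.21 CPM in B7hi and 2378 ± 1021 CPM in B7low, and Mrgprb2, the receptor for basic secretagogues, differed by −4.97 (adjusted p = 0.029). Of the 10 tested members of this list, 8 were lower in B7hi, 9 when adjusted over the list alone (camera adjusted p = 5.9e-14, fry adjusted p = 8.3e-04), against an adjusted p of 0.20 with an estimated correlation. The 8 calls were not all kept with each library left out, since Mrgprb2 lost its call without each saline library. Fewer were also left without both B7low saline 2 and B7hi HDM 2.

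Part of the general mast cell program was lower in B7hi too. Of 20 tested core identity genes, 7 were lower and 0 higher, 9 and 0 adjusted over the list alone (camera adjusted p = 1.3e-04, 0.56 with an estimated correlation). Among them were the IL-33 receptor Il1rl1 (531 ± 13.7 against 2186 ± 299 CPM), Cpa3 (−1.99 ± 0.34) and the IgE receptor chain Fcer1a (−1.85 ± 0.38, adjusted p = 0.0071). Kit did not pass the test (−0.68, adjusted p = 0.25), nor did the progenitor marker Cd34 (0.75, adjusted p = 0.17). The transcript of Itgb7 itself was 846 ± 233 CPM in B7hi and 587 ± 23.3 CPM in B7low (adjusted p = 0.44). Its partner Itgae, which forms the αEβ7 integrin, was at 122 ± 71.1 and 5.02 ± 7.09 CPM (adjusted p = 0.12). The mucosal mast cell proteases Mcpt1 and Mcpt2 varied more within than between groups, with Mcpt1 at 1.75 and 3550 CPM in the 2 B7low libraries (adjusted p = 0.74 and 0.80). The 7 core calls became 2 without B7hi saline 1 and 3 without B7hi saline 2 or B7low saline 1, and Fcer1a was then at adjusted p = 0.051, 0.079 and 0.054.

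**Figure D2:**
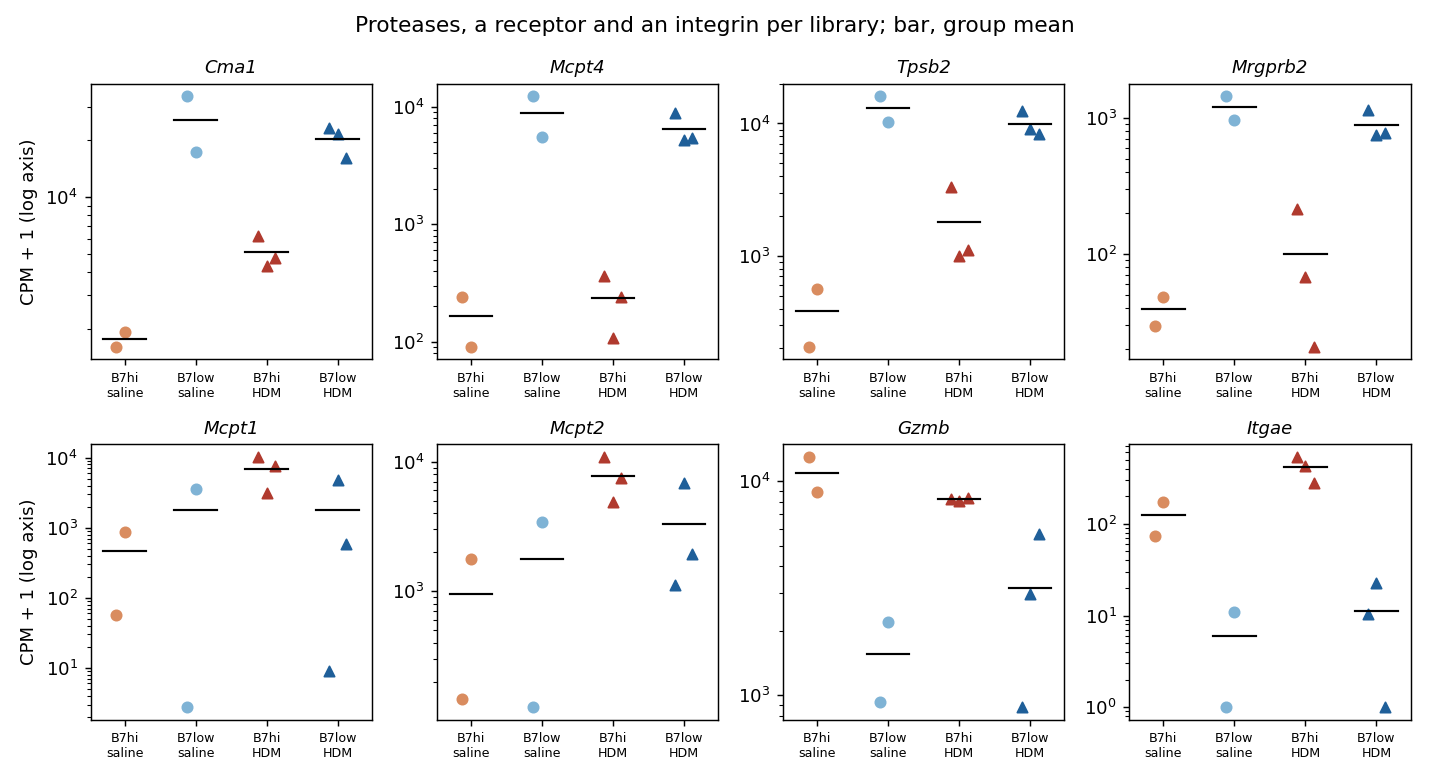
CPM + 1 on a log axis for 6 mast cell protease and receptor genes, the granzyme Gzmb and the integrin Itgae in each library, by group, with bars at the group means. Cma1, Mcpt4 and Tpsb2 were lower in B7hi than in B7low with either challenge, while Mcpt1 ran from 1.75 to 3550 CPM within B7low with saline.

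Adhesion molecules differed in both directions with saline. Of 33 tested adhesion and chemotaxis receptors, 6 were higher in B7hi and 2 lower, 8 and 2 adjusted over the list alone (camera adjusted p = 0.026, 0.56 with an estimated correlation). The integrin α4 chain Itga4, which pairs with β7, stood at 963 ± 27.7 CPM in B7hi and 121 ± 65.1 CPM in B7low. The tetraspanin Cd9 differed by 3.84 ± 0.46. Cadm1, a mast cell adhesion molecule, had 2 counts in B7hi, a level 145-fold lower (95% counting interval 40.3 to 1201). The camera call was lost without B7hi saline 2 (adjusted p = 0.070) or B7low saline 1 (0.19), and with library size alone (0.059).

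Immediate early and dissociation response genes were lower in B7hi with saline, 10 of 33 tested with 0 higher, 15 and 3 adjusted over the list alone (camera adjusted p = 2.8e-04, 0.56 with an estimated correlation). The AP-1 subunit Jun was at 995 ± 469 against 6727 ± 2103 CPM, Fos differed by −3.03 ± 0.53, and the transcription factors Klf4 and Klf2 by −3.85 ± 0.59 and −5.23 ± 0.92. The heparin sulfotransferase Ndst2 (−1.76 ± 0.29), the heparan chain polymerase Ext1 (−2.33 ± 0.42), the urokinase Plau (−5.11 ± 0.70) and the IL-10 receptor chain Il10rb (−2.32 ± 0.31) were also lower. Of the granule and lysosome genes 4 of 26 tested were lower and 1 higher, of heparin synthesis genes 3 of 25 and 0, of matrix and vascular mediators 3 of 13 and 0, and of cytokine receptors 5 of 28 and 1. Adjusted over the list alone, 4, 3, 4 and 5 were lower. The matrix and receptor lists passed camera (adjusted p = 0.043 and 0.042, both 0.56 with an estimated correlation), and both calls were lost without any 1 of the 4 saline libraries, at most at 0.33 (without B7low saline 2) and 0.38 (without B7low saline 1). The 6 basophil markers went both ways. The protease Prss34 (−6.55 ± 0.57) and the receptor Cd200r3 (−3.42 ± 0.41) were lower in B7hi, while the protease Mcpt8 (2.63, adjusted p = 0.073) and Ifitm1 (2.61, 0.054) stood above B7low and passed over the list alone (0.0095 and 0.0074), with DESeq2 and with limma-voom. Without B7hi saline 1 or B7low saline 1, 4 of the 10 immediate early, 1 of the 4 granule and lysosome and 1 of the 3 matrix calls were left, and 2 of the 5 receptor calls were left without these or B7hi saline 2.

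Ribosomal protein genes were higher in B7hi with saline, 35 of 81 with 0 lower (camera adjusted p = 3.6e-15, 0.56 with an estimated correlation), among them Rps19 (1.53 ± 0.32). Adjusted over the list alone, 57 were higher and 1 lower. This count rested on the libraries, with 2 calls without B7hi saline 1 or B7low saline 1 and 3 without B7hi saline 2, and 16 to 20 without B7hi HDM 2, B7hi HDM 3 or B7low HDM 3. With library size alone it was 58. Of 45 cell cycle genes, 41 had a positive log2 fold change with a median of 1.83, and 3 passed the test (Tubb5, Mcm6 and Stmn1), 5 adjusted over the list alone. The camera adjusted p was 1.3e-04 (0.62 with an estimated correlation, 0.097 without B7hi saline 2), and 0 of the 3 calls were left with any saline library left out. Mki67, the proliferation marker, was at 64.8 ± 26.5 and 26.3 ± 14.9 CPM (adjusted p = 0.26).

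The cytokines Il6 (183 ± 1.16 against 56.2 ± 12.7 CPM) and Ccl4 (log2 fold change 2.41 ± 0.52) were higher in B7hi with saline, and the monocyte chemoattractant Ccl2 was lower (−4.57 ± 0.95). Of the 24 tested cytokine genes, 3 were higher and 1 lower, 5 and 1 adjusted over the list alone, and the list itself did not pass camera (adjusted p = 0.29). Leaving out B7low saline 1 put Il6 at adjusted p = 0.071, and Ccl4 was at up to 0.13 (without B7low saline 2) and Ccl2 at up to 0.23 (without B7hi saline 1). Among 11 genes of MHC class II and costimulation, 3 were higher in B7hi, among them H2-Oa (2.97) and H2-DMa (2.43), with 1 of the 3 left without B7hi saline 1 or 2 and 0 without B7low saline 1, with limma-voom or with only the 2 groups in the fit. Summed B cell markers stood at 321 CPM and T cell markers at 204 CPM in B7hi saline 2, against 14.4 and 11.3 CPM in B7hi saline 1. Of 3 epithelial markers, the adhesion protein Cdh1 was higher in B7hi (3.36 ± 0.47).

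Many of the genes with the largest fitted differences with saline had no counts in 1 group. In B7hi and not in B7low were the decoy IL-1 receptor Il1r2 (151 ± 48.6 CPM, at least 58.8-fold higher), Clic4 (at least 11.8-fold), Scarb1 (11.7), St8sia6 (11.3), Gyk (10.3), Eltd1 (10.3) and Ms4a4b (8.95). Eya2 was 87.5-fold higher (interval 15.7 to 3458), the leukotriene B4 receptor Ltb4r1 differed by 5.09 ± 0.77 and Anxa2 by 5.00 ± 0.78. In B7low and not in B7hi were Nkd1 (130 ± 34.3 CPM, at least 140-fold lower in B7hi), the complement component C2 (at least 131-fold), Gpm6a (89.2), Lsamp (55.6), Pcp4l1 (54.3), Fndc8 (31.7) and Ano2 (30.8). Stard13 had 1 count in B7hi and was 1059-fold lower (interval 190 to 41837), and Meis2 was 446-fold lower (80.1 to 17620). Il1r2, St8sia6, Eltd1 and Ms4a4b lost their calls without 3 or more single libraries (adjusted p up to 0.20, Ms4a4b without B7hi saline 2), and Anxa2 without B7low saline 1 (0.051). With limma-voom none of these 10 higher genes passed, from adjusted p = 0.051 (Anxa2) to 0.34 (Eltd1).

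In all, 306 of 10533 genes were higher and 383 lower in B7hi with saline at adjusted p under 0.05, and 2237 had an unadjusted p under 0.05. The CPM ranges of the groups did not overlap for 51.9% of genes, against 33.3% by chance for 2 against 2. With library size alone 67.9% of the called genes were higher, against 44.4% with TMM, since that scaling moved the median log2 fold change by 0.27. The total of 689 fell to 226 without B7hi saline 1, 312 without B7hi saline 2 and 444 without B7low saline 1.

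The next comparison puts the same question after allergen. With HDM, B7hi cells again had lower connective tissue proteases than B7low cells, and the integrin α chains Itgae and Itga4 were higher. Itgae (chromosome 11, 73090583 to 73147446) stood at 413 ± 129 CPM in B7hi and 10.3 ± 10.8 CPM in B7low (SD, n = 3 each; log2 fold change 5.30 ± 0.98, adjusted p = 0.035), the largest fitted difference among the named genes higher in B7hi. Itga4 was at 566 ± 222 against 134 ± 30.8 CPM. Cma1 was at 5074 ± 1005 in B7hi and 20297 ± 3760 CPM in B7low (adjusted p = 7.3e-04), Mcpt4 at 237 ± 128 and 6511 ± 2067 CPM, and Mrgprb1 at 7.19 ± 7.25 and 1627 ± 425 CPM. Of the 10 list members, 6 were lower and 0 higher, 8 and 0 adjusted over the list alone (camera adjusted p = 1.8e-11, fry adjusted p = 0.0059, 0.31 with an estimated correlation). Not all of the 6 calls were kept with each library left out, and fewer were left without both B7low saline 2 and B7hi HDM 2. The Itgae call was lost without each of 7 libraries, at most at adjusted p = 0.18 without B7low HDM 1, with no count filter (0.085) and with only the 2 groups in the fit (0.067), and Tpsb2 (−2.45, adjusted p = 0.029) without each of 6, at most at 0.095.

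Of the core mast cell genes, few passed the test with HDM. Cpa3 (−1.16 ± 0.27) and the kinase Syk (−1.01 ± 0.25) were the 2 of 20 that were lower in B7hi, also over the list alone (camera adjusted p = 0.019, 0.66 with an estimated correlation), and neither was left without B7hi HDM 2, B7hi HDM 3 or B7low HDM 1. The list call was lost without B7hi HDM 2 (0.066), B7hi HDM 3 (0.23) or B7low HDM 2 (0.050). Fcer1a (−0.38, adjusted p = 0.66), Kit (−0.22, 0.80), Itgb7 (−0.22, 0.83), Cd34 (0.43, 0.51) and Mki67 (0.59, 0.67) did not pass. Mrgprb2 was at 99.6 ± 100 and 891 ± 225 CPM (−3.13, adjusted p = 0.086). Mcpt1 was at 6992 ± 3600 CPM in B7hi and 1807 ± 2631 CPM in B7low and Mcpt2 at 7759 ± 3015 and 3300 ± 3107 CPM (adjusted p = 0.80 and 0.79).

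Adhesion genes other than Itga4 and Itgae that passed with HDM were lower in B7hi, namely Cadm1 (−4.89 ± 0.55), the integrin chains Itga9 (−3.10 ± 0.53) and Itgb1 (−1.34 ± 0.30). Of the 33 list members, 2 were higher and 3 lower, 3 and 3 over the list alone, and the list did not pass camera (adjusted p = 0.64). Itgb1 lost its call without each of 3 libraries, at most at 0.13 without B7low HDM 1. Immediate early genes were 6 lower and 1 higher of 33, 11 and 2 adjusted over the list alone (camera adjusted p = 0.0061, 0.66 with an estimated correlation), with Jun at 1662 ± 281 against 4860 ± 1105 CPM, and Klf4 (−2.51), Dusp1 (−1.86) and Klf2 (−4.02) below B7low. Leaving out B7hi HDM 3 ended the list call (adjusted p = 0.15) and left 1 of the 6, and leaving out B7low HDM 1 gave 0.073 and 3 of the 6, as did leaving out B7hi HDM 1 for the count. The 1 higher member lost its call without each of 7 libraries. Il10rb (−1.77 ± 0.25) and Prss34 (−4.00 ± 0.40) were lower with any library left out. Of the other basophil markers Cd200r3 was lower (−1.36), a call lost without each of 4 libraries (up to 0.11), and Mcpt8 (2.12, adjusted p = 0.11, but 0.011 over the list alone, and past the threshold with DESeq2 and limma-voom) and Ifitm1 (1.09, 0.41) pointed the other way. Skil, an antagonist of Smad signalling, was higher in B7hi (1.27 ± 0.23), 1 of 2 such members among 14 TGF-beta response genes.

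Ribosomal protein genes were again higher in B7hi, 28 of 81 with 0 lower, 73 and 0 adjusted over the list alone (camera adjusted p = 4.4e-33, fry adjusted p = 0.032, 0.66 with an estimated correlation), among them Rps24 (1.17 ± 0.22) and Rpl23a (1.08 ± 0.21). The count ranged from 1 without B7hi HDM 2 to 43 without B7low HDM 2. Of 45 cell cycle genes, 42 had a positive log2 fold change and 0 passed, with Stmn1 nearest (1.44, adjusted p = 0.073). The list's camera adjusted p of 3.4e-04 (0.68 with an estimated correlation) became 0.36 without B7hi HDM 3 and 0.17 without B7low HDM 1.

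B cell markers were lower in B7hi with HDM. Of 6 tested, Cd79b (5.97 ± 3.56 against 85.7 ± 48.5 CPM), Ms4a1 (3.95 ± 5.16 against 71.2 ± 32.6 CPM) and Cd79a (−5.95 ± 1.24) passed, 5 adjusted over the list alone (camera adjusted p = 3.4e-04, 0.66 with an estimated correlation). Their sum was 607, 380 and 80.9 CPM in the 3 B7low HDM libraries. Genes of MHC class II summed to 1791, 1713 and 440 CPM in the same libraries, and endothelial markers to 567, 191 and 99.2 CPM. Without B7hi HDM 3 only 1 of the 3 B cell calls was left, and without B7low HDM 3 there were 5, and Cd79a was at 0.28 with limma-voom.

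**Figure D3:**
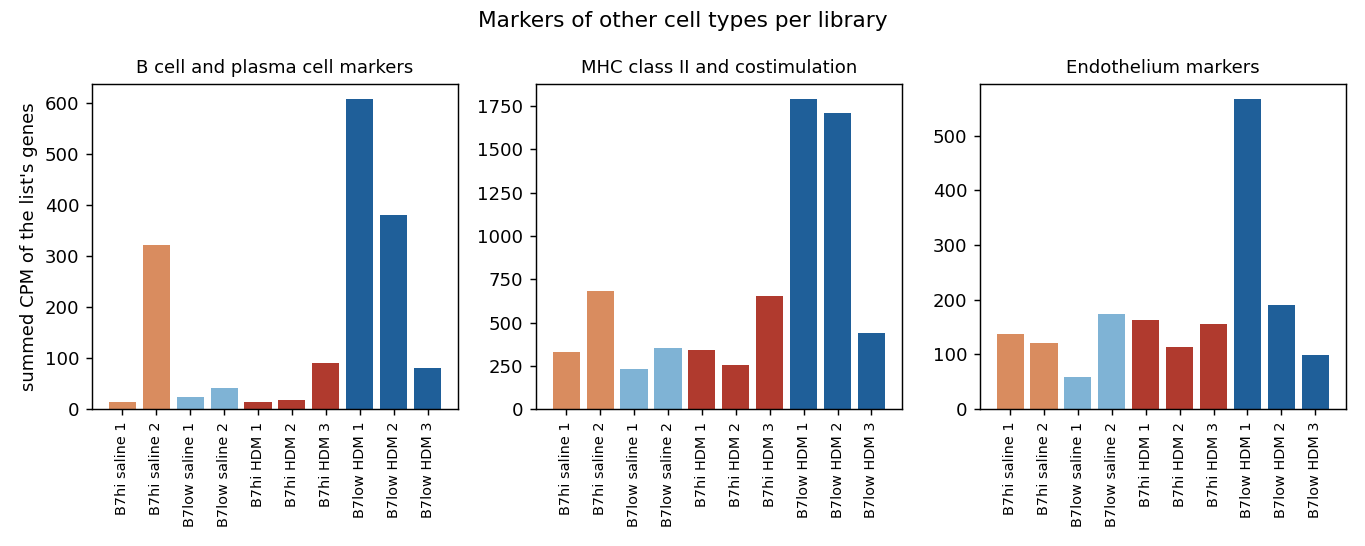
Summed CPM of B cell and plasma cell markers, MHC class II genes and endothelial markers in each of the 10 libraries. B7low HDM 1 and 2 had the highest B cell sums (607 and 380 CPM) and MHC class II sums (1791 and 1713 CPM), and B7low HDM 1 the highest endothelial sum (567 CPM).

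The other genes with the largest positive differences with HDM were the costimulatory receptor Tnfrsf9 (3.24 ± 0.78), Raver2 (2.40), the growth factor receptor Pdgfrb (2.38 ± 0.41), Fgl2 (423 ± 73.4 against 86.9 ± 17.9 CPM), Bmp7 (2.03), Galm (2.02), the inhibitory receptor Havcr2 (1.83) and the proapoptotic Bcl2l11 (1.64). Pdgfrb and Fgl2 kept their calls with any library left out. Bmp7 lost its call without each of 9 libraries (edgeR adjusted p up to 0.22), Tnfrsf9 without each of 5 (0.25) and Bcl2l11 without each of 4 (0.10). Havcr2 lost it without each of 3 (0.21), Raver2 without each of 2 (0.078) and Galm without 1 (0.054). These highest values were without B7hi HDM 1, and for Bcl2l11 without B7low HDM 2. With limma-voom Tnfrsf9, Bmp7 and Havcr2 were at 0.16, 0.065 and 0.084. Without counts in B7hi were Faim3 (at least 53.5-fold lower), Crispld2 (53.4), Stk32b (37.8) and Evc (24.2). Faim3 had 74.5, 54.6 and 5.69 CPM in the 3 B7low HDM libraries, highest where the B cell markers were. With 1 or 2 counts in B7hi, Stard13 was 634-fold lower (interval 114 to 25030), C2 301-fold (54.1 to 11897), Bmp2 192-fold (53.1 to 1585), the B cell adaptor Blnk 168-fold (30.2 to 6640) and Kcnq1 118-fold (32.8 to 978). Faim3 lost its call without each of 5 libraries (up to 0.11, without B7hi HDM 3), Evc without each of 4 (0.084, without B7low HDM 1), and Bmp2 (0.095) and Blnk (0.075) without B7hi HDM 1 or B7hi HDM 3. With limma-voom Faim3, Crispld2, Bmp2 and Blnk were at 0.20, 0.066, 0.11 and 0.077. Kcnq1 (chromosome 7, 143106362 to 143427042) spans its antisense transcript Kcnq1ot1 (143203458 to 143296549), which unstranded counts might not separate. The B7hi HDM libraries had 1290, 6199 and 2056 Kcnq1ot1 counts with 2, 0 and 0 of Kcnq1. In B7low HDM, 1746, 3006 and 4012 Kcnq1ot1 counts went with 67, 81 and 88 of Kcnq1. These counts argue against Kcnq1ot1 reads as the source of the Kcnq1 difference.

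**Figure D4:**
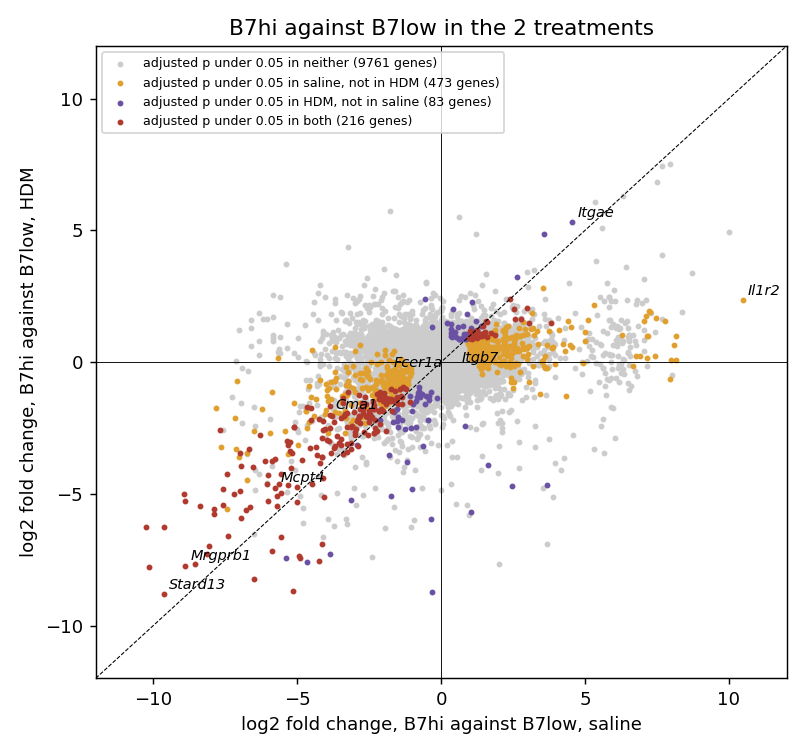
Log2 fold change of B7hi against B7low with saline (x axis) and with HDM (y axis) for the 10533 tested genes, colored by where each was past adjusted p 0.05. The 216 genes called in both lie along the diagonal, beside 473 called with saline and not with HDM and 83 called with HDM and not with saline.

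With HDM, 73 genes were higher and 226 lower in B7hi (1433 with an unadjusted p under 0.05), and the groups' CPM ranges were apart for 20.5% of genes against 10% by chance. The 2 comparisons share no library. They do share the count filter and the fit's estimates of spread, so their calls are not fully independent. Of the genes called with saline, 38 higher and 178 lower were called in the same direction with HDM, against 2.12 and 8.22 expected of independent lists, and 270 of 306 and 367 of 383 had the same sign. The correlation of the log2 fold changes was r = 0.43 (Spearman's rho 0.36) across genes, which are not independent replicates. The total of 299 was 507 with DESeq2, and 156, 147 and 137 without B7hi HDM 2, B7hi HDM 3 and B7low HDM 1.

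The comparison of HDM with saline in B7hi asks how allergen alters the inducible cells. Only Ecm1 (chromosome 3, 95734147 to 95739569), an extracellular matrix glycoprotein, rose past the threshold, from 12.8 ± 1.13 CPM (n = 2) to 80.4 ± 18.7 CPM (n = 3), a log2 fold change of 2.67 ± 0.38 (adjusted p = 0.026), higher in 3 of 3 libraries. The connective tissue list was higher as a set with HDM, with 10 of 10 log2 fold changes positive, a median of 1.50, 0 members past the threshold and 5 past it adjusted over the list alone (camera adjusted p = 2.5e-09, 0.29 with an estimated correlation). Cma1 was at 5074 ± 1005 against 1766 ± 228 CPM (1.52, adjusted p = 0.16), Adora3 at 1.48 (0.13), the tryptase Tpsg1 at 2.38 (0.24) and Tpsb2 at 2.24 (0.51). Among cytokines, Lif, an IL-6 family member, was nearest to the threshold (1.86 ± 0.32, adjusted p = 0.090), with Il6 at 418 ± 44.6 against 183 ± 1.16 CPM (adjusted p = 0.36). That list had 0 members past the threshold and 4 over the list alone (camera adjusted p = 0.045, 0.44 with an estimated correlation). The camera call of the connective tissue list was kept with any library left out, and the cytokine call was lost without B7hi saline 1 (0.090), B7hi HDM 1 (0.23) or B7low HDM 1 (0.052).

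In total 13 of 30 lists passed camera for HDM against saline in B7hi, each with 0 members past the threshold. Mucosal mast cell genes were positive in 5 of 8, with a median of 1.25 and 0 past the threshold over the list alone (camera adjusted p = 0.031, 0.43 with an estimated correlation), and 0.17 without B7hi saline 1 and 0.51 without B7hi HDM 1. Immediate early genes were positive in 27 of 33 (median 0.51, camera adjusted p = 2.7e-05, 0.40 with an estimated correlation), and 0.29 without B7hi saline 1. Core identity genes were positive in 17 of 20, 4 past the threshold over the list alone (camera adjusted p = 0.0031, 0.50 with an estimated correlation), with Il1rl1 at 1.07 (adjusted p = 0.33) and Fcer1a at 1.36 (0.33). This call was lost without B7hi saline 2 (0.25) or B7hi HDM 1 (0.23). TGF-beta response genes, with Skil (1.22, adjusted p = 0.17) and Ldlrad4 (1.94, 0.17), had 0 past the threshold and 3 over the list alone (camera adjusted p = 0.0046, 0.31 with an estimated correlation), and 0.15 without B7hi HDM 1. Progenitor-associated genes were negative in 13 of 16, with Itga4 at −0.77 (adjusted p = 1), and lower as a set (camera adjusted p = 0.0046, 0.29 with an estimated correlation). Stress response genes of the unfolded protein pathway were positive in 18 of 23 (camera adjusted p = 0.010, 0.56 with an estimated correlation), and 0.34 without B7hi saline 1 and 0.19 without B7hi HDM 3. B cell markers were positive in 0 of 6 (camera adjusted p = 0.037, 0.50 with an estimated correlation), with sums of 14.4 and 321 CPM with saline and 13.1, 17.6 and 91.1 CPM with HDM, and the list turned higher without B7hi saline 2 (0.98). Of the remaining genes named in every contrast, Itgae (1.75), Mcpt1 (3.93), Mcpt2 (3.02), Mrgprb2 (1.40), Mcpt4 (0.55), Cpa3 (0.40), Kit (0.19), Cd34 (0.06), Mki67 (−0.05) and Itgb7 (−0.42) were all at adjusted p = 1.

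In all, 1 gene was higher and 0 lower with HDM in B7hi, with 435 at an unadjusted p under 0.05, while DESeq2 called 44 and limma-voom 9. The 435 were no more than chance would give at that cutoff among 10533 genes. CPM ranges of the groups were apart for 20.6% of genes, near the 20% given by chance. Ecm1 lost its call without B7hi saline 1 (adjusted p up to 0.22), B7hi saline 2 or B7low HDM 2, without robust estimation and with only the 2 groups in the fit. The count was 7, 2, 5, 11 and 0 without B7hi saline 2, B7hi HDM 1, B7hi HDM 2, B7hi HDM 3 and B7low HDM 2.

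**Figure D5:**
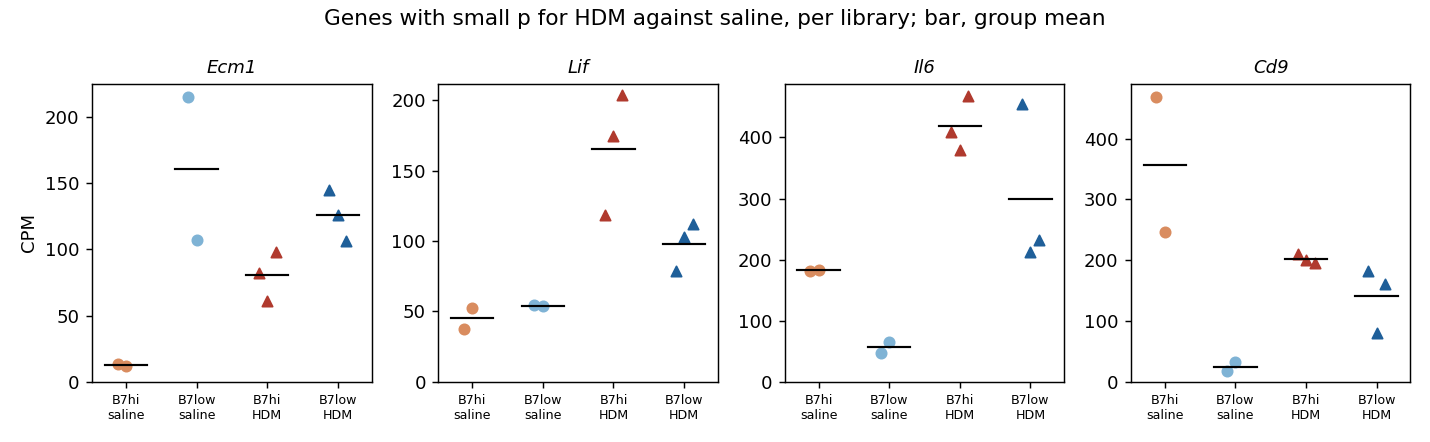
CPM of Ecm1, Lif, Il6 and Cd9 in each library, by group, with bars at the group means. Ecm1 was at 12.8 CPM on average in B7hi with saline and 80.4 CPM with HDM, and Il6 at 56.2 CPM in B7low with saline and 300 CPM with HDM.

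The same comparison in B7low asks how allergen alters the constitutive cells. Il6 (chromosome 5, 30013114 to 30019981), the cytokine, was the only gene past the threshold, at 56.2 ± 12.7 CPM with saline (n = 2) and 300 ± 134 CPM with HDM (n = 3), a log2 fold change of 2.40 ± 0.36 (adjusted p = 0.041), higher in 3 of 3 libraries. Of 24 cytokine genes, 18 were positive and Il6 alone passed, also over the list alone (camera adjusted p = 0.0078, 0.52 with an estimated correlation), with Ccl4 at 1075 ± 581 against 376 ± 19.1 CPM (adjusted p = 0.39). Without B7low saline 1 or B7low saline 2 this list was at 0.058 and 0.27. Cd9 was next to the threshold (141 ± 53.3 against 24.6 ± 10.1 CPM, adjusted p = 0.074). The adhesion list was higher as a set (camera adjusted p = 0.041, 0.65 with an estimated correlation), 3 members over the list alone, and lost the call without each of 4 libraries, at most at 0.61 without B7low saline 1.

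MHC class II and costimulation genes were positive in 11 of 11 in B7low with HDM, with a median of 2.18, 0 past the threshold and 3 over the list alone (camera adjusted p = 0.0011, 0.52 with an estimated correlation). Ctss, a protease of antigen processing, was at 49.1 ± 30.1 CPM against 0.874 ± 1.24 (adjusted p = 0.10) and H2-DMa at 39.1 ± 9.94 against 8.48 ± 4.57 CPM (0.31). B cell markers moved with them (camera adjusted p = 0.0078, 0.65 with an estimated correlation), with Cd79b at 85.7 ± 48.5 against 6.04 ± 3.82 CPM (adjusted p = 0.21). Interferon-stimulated genes were positive in 26 of 30, 3 past the threshold over the list alone (camera adjusted p = 0.0011, 0.74 with an estimated correlation), with the antiviral Rsad2 at 50.1 ± 2.65 against 12.9 ± 4.03 CPM (adjusted p = 0.32). Without B7low saline 1 these lists were at 0.058, 0.23 and 0.068, and the B cell list was at 0.050 without B7low HDM 1. The connective tissue list was lower as a set, positive in 0 of 10 with a median of −0.44 (camera adjusted p = 0.043, 0.74 with an estimated correlation), and lost the call without each of 4 libraries, at most at 0.69 without B7low saline 1.

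The genes named in every contrast did not change past the threshold in B7low. Cma1 was at 20297 ± 3760 CPM with HDM and 25771 ± 12083 CPM with saline (−0.34, adjusted p = 0.77). The log2 fold change was −0.45 for Mcpt4, −0.41 for Tpsb2, −0.44 for Mrgprb2, −0.43 for Cpa3, −0.28 for Kit, −0.11 for Fcer1a, 0.32 for Itgb7, 1.01 for Itgae, 0.03 for Mcpt1, 0.91 for Mcpt2, 0.39 for Cd34 and 0.66 for Mki67, with adjusted p of 0.69 or more. With 1 gene higher and 0 lower, 956 had an unadjusted p under 0.05, and DESeq2 called 12 and limma-voom 0. CPM ranges of the groups were apart for 23.9% of genes against 20% by chance. The Il6 call was lost without either B7low saline library (adjusted p up to 0.22, without B7low saline 2), any B7hi HDM library or B7low HDM 1, and with DESeq2 size factors, only the 2 groups in the fit, no robust estimation or limma-voom (0.055, 0.14, 0.058 and 0.88). The count was 13 without B7low saline 1, 3 without B7low HDM 2 and 2 without B7hi saline 1 or B7low HDM 3.

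The last comparison tests whether HDM acted differently on the 2 populations. No gene passed for the interaction with edgeR, 901 had an unadjusted p under 0.05, and DESeq2 called 28 and limma-voom 0. Among the nearest were Ecm1 (3.03) and Cd9 (−3.32), both at adjusted p = 0.054. The connective tissue list had 10 of 10 positive interaction values with a median of 1.99, 0 members past the threshold and 5 over the list alone (camera adjusted p = 6.3e-07, 0.42 with an estimated correlation), and it was 1 of 7 lists of 30 past camera with the preset correlation. Its call was kept with any library left out. Cma1 was at 1.87 (adjusted p = 0.22), Tpsb2 at 2.65 (0.40), Adora3 at 2.11 (0.15) and H2-DMa at −3.02 (0.22). Of the other fixed genes, Mcpt1 (3.90), Mcpt2 (2.12), Mrgprb2 (1.84), Fcer1a (1.47), Mcpt4 (1.00), Cpa3 (0.84), Itgae (0.74), Kit (0.47), Cd34 (−0.33), Mki67 (−0.71) and Itgb7 (−0.74) were at adjusted p of 0.42 or more. Across genes, the HDM effects in B7hi and in B7low had a correlation of r = −0.15 (rho −0.14). The count was 1 without B7low saline 2 and B7hi HDM 2 together, 3 without B7hi saline 2 or B7hi HDM 3, 2 without B7low saline 1 and 1 without B7hi saline 1, B7low saline 2 or B7low HDM 2.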

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

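The tests of B7low cells, scaling, B cells and macrophages in this part were chosen only after the results were seen. A total of 7 gene lists stood out because the HDM effect in B7hi differed from that in B7low by the interaction test (camera, preset correlation, edgeR fit). None passed with an estimated correlation (adjusted p of 0.42 or more), and the other splits of the libraries bear only on the comparison of B7hi and B7low with HDM. There the real split gave 299 genes, as many as in 1 of 10 splits, and the highest of the other splits gave 2, which are too few splits for a share under 0.05.

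The connective tissue mast cell proteases and receptors had the lowest interaction p (adjusted p = 6.3e-07), with a median log2 fold change of 1.50 with HDM in B7hi and −0.44 in B7low. Admixed B7low cells would bring all of their abundant transcripts, at a share of 13.6% to 24.0% by Cma1, but the summed rise of Mcpt4, Mrgprb1 and Mrgprb2 was 18.1%, −2.37% and 3.76% of what these shares need, which argues against B7low cells as the whole source. The members differed, with mean implied shares of 1.14% for Mcpt4 and 0.108% for Mrgprb1 against 15.0% for Tpsb2, 23.6% for Tpsab1, 34.3% for Adora3 and 36.0% for Tpsg1, so only a small admixture stays open (in B7hi HDM 1, 3.12% by Mcpt4 and 0.590% by Mrgprb1, though 20.4% by Mrgprb2). The lowest median over 3 scalings was 1.33 (library size alone), so scaling does not account for the rise either. It may be a partial shift of B7hi cells toward this program with allergen, as a hypothesis only, since the mix of cell states within the sort was not measured and 0 members passed on their own.

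B cell and plasma cell markers (adjusted p = 0.0014, median −5.56) and MHC class II and costimulation genes (adjusted p = 0.0019, median −3.02) differed the other way, with the highest sums in B7low HDM 1 and 2. As B cells or their RNA would bring, 9 further B lineage genes outside the lists summed to 424 and 284 CPM there, the lower of these 2.202-fold the highest of the other 8 libraries (129 CPM). Macrophage and monocyte markers reached 50.2 CPM there, 0.557 of the highest of the other 8 libraries. That highest sum, in B7hi HDM 2, rests mostly on Ccr2 (39 counts), and the other members had few counts in any library. The sums thus cannot decide whether such cells were present in B7low HDM 1 and 2. B cells or their RNA are a likely source of the B cell markers, which stood at 80.9 CPM in B7low HDM 3. The source of the MHC class II genes stays open, since a rise in mast cells themselves was not tested and the dendritic cell sums of these libraries (217 and 121 CPM) rest mostly on Ccr7 (165 and 93.7 CPM), which B cells express too.

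Adhesion and chemotaxis receptors had an interaction adjusted p of 0.0014 (median −0.92), and 0.13 without B7low saline 1. Core mast cell identity genes were at 0.0098 (median 0.49), and at 0.12 without B7hi saline 2, 0.45 without B7low saline 1 and 0.097 without B7hi HDM 1. The 3 epithelial markers were at 0.026 (median −2.67), and immediate early and dissociation genes at 0.037 (median 0.58), with up to 0.45 and 0.72 when a library was left out (without B7low saline 1 and B7hi saline 1).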

How the results depend on the processing

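The runs without Rn45s and without the 2 libraries highest in Kcnq1ot1 were chosen after seeing the data. The named genes past the threshold, 65 with saline, 48 with HDM and 1 each for HDM against saline in B7hi and in B7low, kept their direction in each alternative that tested them. With each library left out in turn, 39, 20, 0 and 0 of them kept their call throughout. A group left with 1 library is assumed to vary like the others. The cause of the shifts below was not tested, except that settings with fewer libraries or the 2 groups compared hold less information on spread.

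With saline, 689 genes (306 higher, 383 lower) became 1078 without a count filter (606 higher) and 377 with only the 2 groups compared (124 and 253). Higher genes numbered 655 with library size only, 142 with limma-voom and 191 without the 2 libraries. With each library left out the total was 226 to 685, 80 to 305 higher and 146 to 427 lower. With HDM, 299 (73 higher, 226 lower) became 507 with DESeq2 (163 and 344) and 548 without a filter (175 and 373). Higher genes numbered 119 with limma-voom and 29 without the 2 libraries. With each library left out the total was 137 to 368, 12 to 112 higher and 112 to 256 lower.

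For HDM against saline in B7hi, 1 gene became 44 with DESeq2, 89 without a filter, 9 with limma-voom, 5 without the 2 libraries, and 0 with only the 2 groups compared or without robust estimation, and 0 (without B7low HDM 2) to 11 (without B7hi HDM 3) with a library left out. In B7low, 1 became 12 with DESeq2, 112 without a filter, 4 with library size only, 3 with at least 5 CPM in 2 samples, and 0 with DESeq2 size factors, limma-voom, only the 2 groups compared, no robust estimation or without the 2 libraries, and 0 to 13 (without B7low saline 1) with a library left out. The interaction's 0 became 28 with DESeq2, 143 without a filter, 2 with library size only, 3 with at least 5 CPM in 2 samples, 1 without the 2 libraries, and 0 to 3 with a library left out. Library size only moved the median log2 fold change by −0.16 for HDM against saline in B7hi, 0.13 in B7low and −0.29 for the interaction.

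With a replicate block, HDM against saline gave 6 genes in B7hi and 2 in B7low, with log2 fold changes of 0.0789 for Fcer1a and 0.0276 for Mrgprb2 in B7low. The numbers were not taken to pair the libraries, since the labels do not say what they share and the correlation of same-numbered B7hi and B7low libraries was 0.02, −0.11 and −0.05 with HDM. With saline it was 0.04, a single value, since centring groups of 2 makes both pairs equal.

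The direction turned for 40 values of named genes that were not called. With saline, Mcpt1 was 1.19 with limma-voom, 7.95 without the 2 libraries and −4.97 to 7.98 with a library left out, and Mcpt2 2.90 and −3.59 to 2.94. With HDM, Itgb7 was 0.0553 without the 2 libraries and −0.50 to 0.0440 with a library left out, and Mki67 −0.29 to 0.99. For HDM against saline in B7hi, Cd34 was −0.11 with library size only, −0.0244 with limma-voom and −0.28 to 0.28 with a library left out, Mki67 0.0818 without the 2 libraries and −0.92 to 0.44, and Kit −0.17 to 0.48. In B7low, Fcer1a was 0.0295 with library size only and −0.37 to 0.0761 with a library left out, Mcpt1 −0.0336 with DESeq2, −0.0317 with its size factors and −2.61 to 9.95, Mcpt2 −0.25 to 4.72, Cma1 −0.75 to 0.27, Cpa3 −0.79 to 0.10, Mcpt4 −0.91 to 0.28 and Itgae −0.63 to 6.71. For the interaction, without the 2 libraries and with a library left out, Itgae was −5.10 and −4.96 to 2.41, Mcpt1 −5.67 and −6.03 to 6.93, and Mcpt2 −1.45 and −1.70 to 4.83. The B cell marker list for HDM against saline in B7hi turned without B7hi saline 2 (camera adjusted p = 0.98), with a lowest p of 3.2e-08 with a library left out.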

Other observations

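The genes of the serotonin pathway, and the tests of B7hi cells, dissociation and a smaller difference with HDM, were chosen only after the values were seen. The serotonin transporter Slc6a4 stood at 2.27 and 6.26 CPM in B7hi and 608 and 396 CPM in B7low with saline, and at 5.48 to 9.79 CPM in B7hi and 273 to 451 CPM in B7low with HDM (edgeR adjusted p = 5.2e-07 and 3.3e-07). Tph1, which makes the serotonin precursor, was at 39.3 and 152 CPM in B7hi with saline and at 943, 585 and 749 CPM with HDM. The HDM values were near the 593 to 1189 CPM of the B7low libraries. For HDM against saline in B7hi its adjusted p was 0.090 with edgeR and 0.0079 with limma-voom. Leaving out B7hi saline 2, the higher saline value, gave a log2 fold change of 4.27. With any of the other libraries left out Tph1 did not pass. Ddc, the next enzyme, was at 2.27 and 11.5 CPM and then 71.3, 21.5 and 71.2 CPM in B7hi (edgeR adjusted p = 0.11). It was at 0.027 without B7hi HDM 2, the lowest of the HDM values. Leaving out B7hi saline 2, the higher saline value, gave a log2 fold change of 4.58. Ddc did not pass with any of the other libraries left out. The vesicular monoamine transporter Slc18a2 was at 870 to 1474 CPM in all 10 libraries.

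The mucosal proteases varied between libraries of the same group. Mcpt1 was at 56.7 and 861 CPM in B7hi and 1.75 and 3550 CPM in B7low with saline, and at 10237, 3120 and 7618 CPM in B7hi and 8.13, 4826 and 587 CPM in B7low with HDM. Granzyme B, Gzmb, was at 12984 and 8924 CPM in B7hi and 930 and 2194 CPM in B7low with saline, and at 8107 to 8375 CPM in B7hi and 877, 2966 and 5665 CPM in B7low with HDM.

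Il6 was higher in B7low with HDM than with saline by 244 CPM. A stronger response to dissociation and sorting would raise the immediate early and dissociation genes by about as much as Il6 (2.40), but their median log2 fold change was −0.0595 with an SD of 0.86 between 33 members, which argues against it as the whole cause. The rise of Il6 needs a share of B7hi cells of 110%, 43.2% and 48.7% in the 3 libraries, and the median share implied by 278 genes higher in B7hi with saline, which choosing them on the saline libraries raises, was 26.8%, 108% and 104% of that, while Itgae allows at most 7.72% of such cells. B7hi cells thus fall short in B7low HDM 1. At the share that Itgae allows, they would bring at most 36.1 CPM of Il6. In B7low HDM 2 and 3 Itgae and the 278 genes disagree, so B7hi cells stay open there. An effect of allergen on B7low cells stays open too, and the call was lost without each of 6 libraries (adjusted p up to 0.22, without B7low saline 2).

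A hypothesis was that the populations differ less with HDM than with saline. Of the 226 genes lower in B7hi with HDM, 153 (67.7%) had a larger difference with saline, although they were chosen on the HDM libraries. Their medians were −2.69 with saline and −2.39 with HDM (differences of mean log2 CPM with a prior count, not the fitted log2 fold changes). Both medians rest on TMM. Library size alone moved the median log2 fold change over all tested genes by 0.27 with saline and −0.02 with HDM. Such shifts would close most of the gap, while DESeq2 size factors moved that median the other way, by −0.08 and −0.01. With TMM the values go with a smaller difference, which B7hi cells in B7low HDM 2 and 3, left open above, would also give. These libraries were at 15.0 and 15.4 on the first principal component, against 45.0 for B7low HDM 1 and 65.1 and 64.8 for B7low with saline. The values thus do not tell a change in the cells from such a mix or from scaling. Of the 73 genes higher in B7hi with HDM, 36 (49.3%) had a larger difference with saline, with medians of 1.10 for both challenges, which decides nothing, since choosing the genes on the HDM libraries raises their difference with HDM.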
